A study of Mus musculus with 2 samples.

How the data were processed

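Dura mater of female mice was profiled by droplet-based single-cell RNA sequencing after sham surgery (sham) and 14 days after ligature of the jugular veins (JVL-14). How long after sham surgery the dura was taken is not stated here. Per the labels' protocols, mice were perfused, the dura was peeled from the skullcap and digested with collagenase and DNase, and cells of 2 meninges were combined per well. Cells were then sorted as viable singlets, and 20000 cells were loaded per library. Each of the 2 groups has 1 library, and the number of mice behind each is not given in the sources used here. The sort and the peeling can set which cells are seen: the skull next to the dura holds bone marrow, and other tissue at the skullcap can come away with it.

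The deposited files hold counts of unique molecular identifiers (UMIs) per gene and barcode, not normalised, for 33696 genes, and per the file headers they were written by Cell Ranger 8.0.0. The reads were aligned to mm39, per the submitters' processing notes, and the gene annotation used is not given in the sources used here. The deposited counts cover filtered barcodes only, and every one had at least 500 UMIs. Genes were matched by the symbols in the files, and for the 26 symbols that repeat an earlier 1 the gene with more UMIs was used. A reference of the same build was not used here, so no coordinates are given.

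The sham library held 5495 barcodes and 33996641 UMIs, and the JVL-14 library 3004 barcodes and 18796260 UMIs. Barcodes with under 200 genes (266 and 244) or over 10% mitochondrial UMIs were left out. Scrublet (in scanpy 1.11.5) was run per library. Its automatic threshold marked 0.121% and 0.230% of barcodes, under the preset minimum of 0.5%, so the barcodes in the top 5% of scores, ties included, were removed as doublets (279 and 137). Doublets that score low can remain. This left 4672 sham and 2471 JVL-14 cells, with medians of 4502.5 and 4530 UMIs per cell. Medians differed more within classes, as with 19197 and 7637.5 in neutrophil precursors, 7058 and 5454 in neutrophils, 5320.5 and 4656 in fibroblasts and 2364 and 2864 in macrophages.

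Cells of both libraries were clustered together without integration. UMIs were scaled to 10000 per cell and log transformed, 2000 variable genes were chosen with the library as batch, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 35 clusters. No cell annotation by the authors was used here. Names were rebuilt from marker genes fixed for 30 classes, so shares may differ from those in the study for that reason. Fibroblast-like cells are called fibroblasts here, and likewise for the other classes. A cluster was named for its best-scoring class if the mean score was at least 0.5, at least 3 markers were raised at least 1.5-fold and detected in at least 10% of its cells, and its 10 leading genes held no more markers of another class than of its own. A cluster whose cells had a median under 0.333 times the UMIs of their library and no marker of its class among those genes stayed unnamed. In all, 31 clusters were named and fell into 18 classes, and 4 stayed unnamed (11.6% of sham and 6.56% of JVL-14 cells). The numeric limits for naming were not fixed beforehand.

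Class shares of retained cells carry exact Clopper-Pearson 95% intervals. For genes, UMIs were summed per class and library and expressed per 1e6 UMIs of the class (CPM), and the ratio JVL-14 over sham carries an exact conditional binomial 95% interval. Classes with at least 50 cells in each library were compared gene by gene. Log2 ratios had 0.5 added to each count. A gene list was summarised by the median log2 ratio of its measured members (mean CPM and summed count of at least 20), and lists with under 5 measured members were not summarised. The interval of a median came from 2000 Poisson redraws of the counts. Its percentile was taken among 10000 random lists matched on expression in 20 bins, as a description of these libraries. All intervals cover counting error only. Those of genes and lists take each UMI as independent, so they leave out how UMIs are spread over cells. With 1 library per group, no test was made and no p-value is given, and differences between mice, dissections and library preparations cannot be separated from the procedure.

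The groups, the filters, the markers, 34 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, in each compared class among the vascular, fibroblast, myeloid, B, T and innate lymphoid ones, the 5 genes with the highest and the 5 with the lowest CPM ratio among genes with at least 30 UMIs and 50 CPM in the library where they were higher and at least 0.5 times the CPM of all retained cells there. Counts under 3 were set to 3 for the ranking. Mitochondrial, ribosomal, haemoglobin and immunoglobulin genes, Xist and unnamed gene models were left out. It took 50 genes in 5 classes. For 27 of them, at least 50% of the UMIs in the higher library lay in 5 cells. Apart from Hspa1a and Hspa1b in monocytes, Bpifa1 in fibroblasts and Jchain in B cells, these 27 are not described, and this limit was set after their values and a first recomputation under the alternatives were seen. Of the 27, 15 changed direction in at least 1 alternative. List examples are 2 to 4 members with the largest log2 ratio in size and at least 20 UMIs in the higher library, and genes named beyond these rules were chosen after their values were seen. Of 76 pairs of list and class that could be summarised, 44 are described and 32 are not, also chosen after their values were seen.

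The ratio, interval and list steps were tested on simulated counts with 200 changed genes. These counts were Poisson draws of class sums, the model behind the intervals, with no spread between cells. They check the steps and not how well the intervals hold in real cells. In the simulated fibroblast comparison (6233 genes), intervals lay on the right side of 1 for 100% of genes changed 2-fold. In simulated macrophages (5177 genes) this held for 96% and in simulated B cells (5142 genes) for 73% of genes changed 2-fold. Alternatives covered the gene and mitochondrial filters, doublet removal, clustering resolution, clustering per library, naming per cell, the denominator, scaling by edgeR 4.0.16 (TMM) or the median of ratios, averaging over cells, thinning each cell to 1000 UMIs, the count added and the expression limit, and, chosen after the data were seen, a denominator without tissues outside the dura, unnamed clusters placed in their best-scoring class, clusters of 1 library left out, fibroblast cluster 19 left out, and ratios averaged within clusters. GC content came from GENCODE M21 transcripts, matched by gene identifier. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.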

Results

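Single-cell transcriptomes were taken of the mouse dura mater, the outermost of the membranes around the brain. Sham surgery was compared with ligature of the jugular veins 14 days earlier, and the time since sham surgery is not stated here. The question was how the cells of the dura differ once venous outflow through these veins is blocked. Each group has 1 library, with 4672 retained cells in sham and 2471 in JVL-14. Total counts were 33996641 UMIs in sham and 18796260 in JVL-14 over all deposited barcodes. No difference given here has a replicate check. Brackets after a value give its 95% interval, which covers counting error only, and ratios are JVL-14 over sham. For genes and lists the interval leaves out the spread between cells and is too narrow where few cells hold many of the UMIs.

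Cells of the B lineage, erythroid cells and neutrophil precursors made up a larger part of the JVL-14 library. B lineage cells were 7.77% of sham cells (363, 7.02% to 8.57%) and 15.7% of JVL-14 cells (387, 14.3% to 17.2%), a ratio of 2.02 (1.74 to 2.33). Both Rag1-high and cycling precursors (165 and 196 cells, ratio 2.25, 1.82 to 2.78) and mature B cells (198 and 191 cells, ratio 1.82, 1.49 to 2.24) were higher. Elane- and Mpo-high neutrophil precursors had a ratio of 2.71 (1.93 to 3.83), from 60 and 86 cells. Erythroid cells had a ratio of 2.70 (1.99 to 3.67), from 75 and 107 cells. Of these, cluster 34 held 12 and 77 (ratio 12.1, 6.56 to 24.5) and cluster 29 held 63 and 30 (ratio 0.900, 0.563 to 1.41). Such precursors are found in bone marrow, and whether these cells came from marrow or from the dura itself was not tested. The neutrophil precursor ratio was 0.633 (0.227 to 1.55) without doublet removal, where 21 and 7 cells kept that name. There a cluster led by H2ac8 and Pclaf (111 and 152 cells) stayed unnamed. No alternative gave a neutrophil precursor ratio above 2.71. The erythroid ratio was 4.90 when at least 500 genes per cell were required. The B cell precursor ratio was 3.94 with at most 5% mitochondrial UMIs, where a cluster led by Arl5c and Vpreb3 (147 and 169 cells) was named B cell.

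The main stromal and myeloid classes held similar parts of both libraries. Fibroblasts, the matrix-producing cells of the dura, were 30.1% of sham (28.8% to 31.5%) and 27.5% of JVL-14 cells (25.7% to 29.3%). Macrophages were 14.3% (13.3% to 15.3%) and 13.2% (11.8% to 14.5%), monocytes 4.97% and 4.01%, and mature and Camp-high neutrophils together 3.87% and 4.53%. The interval of the ratio held 1 for macrophages (0.921, 0.804 to 1.05), monocytes (0.807, 0.631 to 1.03) and neutrophils (1.17, 0.916 to 1.49), and for fibroblasts (0.912) it ran from 0.831 to just under 1. The fibroblast ratio was 1.02 without marrow classes. The neutrophil ratio was 0.491 with the libraries clustered separately, where a JVL-14 cluster of 64 cells led by Camp scored best as neutrophils but stayed unnamed. In that setting no JVL-14 cluster took the name of monocytes or of natural killer or innate lymphoid cells, so both ratios were 0, and the T cell ratio was 3.47. Lower in JVL-14 were blood endothelial cells (168 and 46 cells, ratio 0.518, 0.365 to 0.721) and natural killer or innate lymphoid cells (140 and 48, ratio 0.648, 0.457 to 0.906). The latter class is cluster 14, led by Areg and Gata3. Gzma and Nkg7, natural killer markers of that class, were leading genes of cluster 8, which was named T cells, so a lower natural killer share is not shown. Of the endothelial cells, 71 and 3 lay in cluster 22, whose cells had a median of 0.335 times the UMIs of their library, next to the limit of 0.333 for a name, and 97 and 43 in cluster 12 (ratio 0.838, 0.571 to 1.21). Where the filters or doublet removal were changed, the cluster with the leading genes of cluster 22 stayed unnamed, and the endothelial ratio was up to 0.848. Cluster 22 lay almost wholly in sham, as did the skeletal muscle cells described below. Whether its cells came from the dura was not tested, so the lower endothelial share may not be one of the dura. T cells (42 and 28), mast cells (72 and 26), osteoblast lineage cells (83 and 57) and mural cells (23 and 17) had ratios of 1.26, 0.683, 1.30 and 1.40, each with an interval that held 1. Schwann or glial cells had a ratio of 1.61 (1.17 to 2.22).

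**Figure D1:**
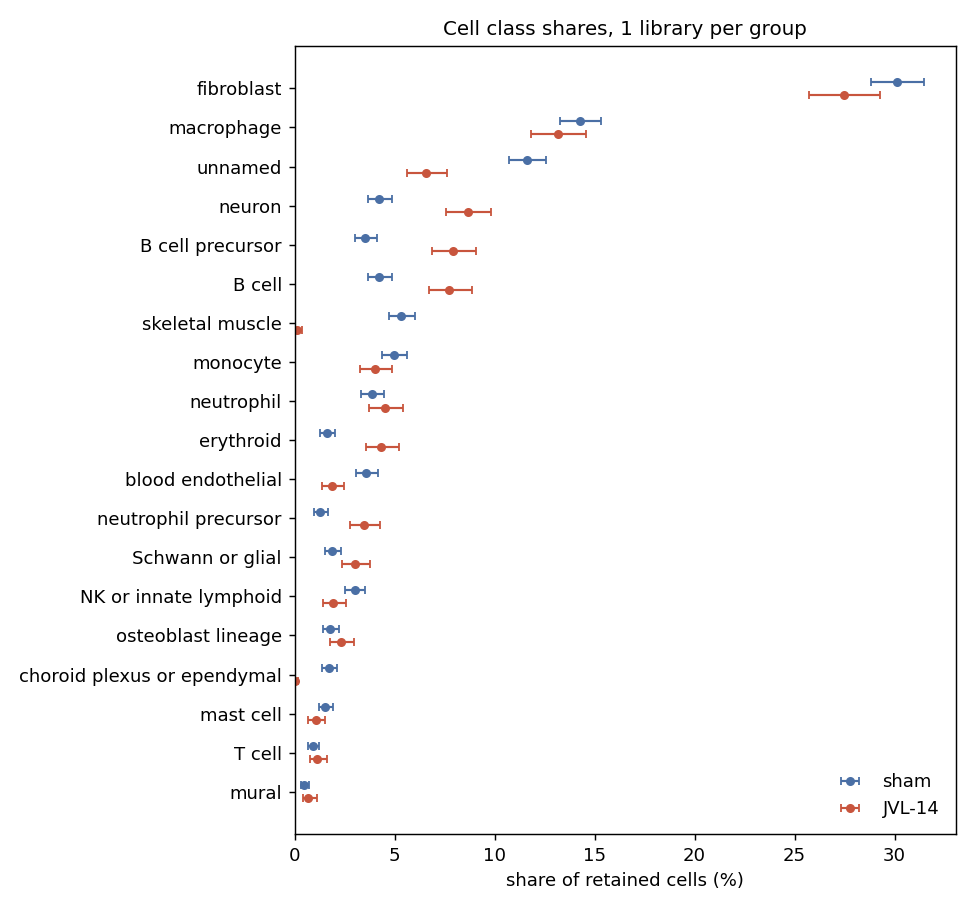
Share of retained cells (%) in each cell class for the sham (blue) and JVL-14 (red) library, 1 library per group, with exact 95% binomial intervals. B cells, B cell precursors, erythroid cells and neutrophil precursors lie higher in JVL-14, and skeletal muscle and choroid plexus cells were found almost wholly in sham.

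The libraries also differed in cells that are not part of the dura. Skeletal muscle cells numbered 249 in sham and 3 in JVL-14, a ratio of 0.0228 (0.00467 to 0.0673). Choroid plexus cells numbered 80 in sham and 0 in JVL-14, which allows a share of up to 0.121% and makes the ratio at most 0.0709. Olfactory-type neurons, led by Omp and Stoml3, were 4.24% of sham and 8.66% of JVL-14 cells (ratio 2.04, 1.68 to 2.49). Muscle transcripts in cells of other classes were also higher in sham, and free RNA and remaining doublets were not told apart. Acta1, the actin of skeletal muscle, stood at 93.6 CPM in sham and 1.29 CPM in JVL-14 fibroblasts, and Hbb-bs, a haemoglobin chain, at 341 and 735 CPM. Hbb-bs went the other way in blood endothelial cells (14554 and 286 CPM) and neurons (3583 and 214 CPM). Omp, of olfactory neurons, went the other way from its cells, at 14.6 and 3.30 CPM in macrophages. Bpifa1, a leading gene of fibroblast cluster 1, had 5242 UMIs in 6 JVL-14 fibroblasts and 1 UMI in sham. Unnamed clusters held 543 and 162 cells, chiefly cluster 23 with leading genes Slc4a10 and Slc47a1 and markers of both fibroblasts and the arachnoid barrier (396 and 127 cells, ratio 0.606, 0.493 to 0.742).

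Fibroblasts of the JVL-14 library carried more transcripts of bone morphogenetic protein (BMP) target genes and fewer of inflammatory, interferon-induced and antigen presentation genes. Of 12 measured BMP response genes, 8 were higher and 4 lower, with a median log2 ratio of 0.32 (0.15 to 0.44), at percentile 100 of matched random lists. Id1 (ENSMUSG00000042745), a direct BMP target, stood at 276 CPM in sham and 486 CPM in JVL-14 (ratio 1.76, 1.66 to 1.87). Id2 had a ratio of 1.58 (1.52 to 1.65) and Smad7, an inhibitor of the pathway, of 1.53 (1.33 to 1.75), while Tmem100 was lower (0.634, 0.581 to 0.691). The BMP median kept its sign in all 14 alternatives, from 0.12 to 0.42. Among single clusters it was 0.39 in cluster 0, 0.30 in cluster 1, 0.40 in cluster 7 and 0.46 in cluster 19, but -0.31 in cluster 21 (67 and 46 cells).

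Of 25 measured interferon response genes, 24 were lower in JVL-14 fibroblasts, 22 of them beyond counting error, with a median log2 ratio of -0.52 (-0.63 to -0.46) at percentile 0. Examples are the transcription factor Irf7 (ENSMUSG00000025498), at -1.07, Ifi27l2a at -1.06, Gbp2 at -0.88 and Isg15 at -0.88. Of the JVL-14 UMIs, 44.0% for Irf7 and 47.4% for Isg15 lay in 5 cells. Cluster 19, whose leading genes are interferon-induced, held 114 sham and 26 JVL-14 cells, and without it the median was -0.17. It was -0.45 in cluster 0 (428 and 244 cells), 0.09 in cluster 1 (395 and 207 cells), 0.18 in cluster 7 (342 and 154 cells), 0.13 in cluster 19 and -0.12 in cluster 21 (67 and 46 cells). Averaged within fibroblast clusters, the interferon median was 0.01, with Irf7 at 0.24 and Isg15 at 0.07. In such averages, the 0.5 added to each count pulls genes with few UMIs in a cluster above 0 where sham had more UMIs. MHC class I genes were lower in 11 of 12 (median -0.26, -0.35 to -0.17), with Tap1 at -0.69, and their median averaged within clusters was -0.02. MHC class II genes were lower in 5 of 6 (median -0.26, -0.36 to -0.13), but their median was 0.10 in thinned cells and 0.21 averaged within clusters. Their member Cd74 stood at 169 and 139 CPM in fibroblasts, against 22562 and 26265 CPM in macrophages. Free RNA of other classes and remaining doublets were thus not told apart from expression of these genes by fibroblasts. Of 12 inflammatory cytokine and NF-kB genes, 9 were lower (median -0.66, -0.78 to -0.45, percentile 0), with the chemokines Ccl2 at -3.13, Ccl11 at -1.80 and Cxcl1 at -1.66. The inflammatory median was -0.12 averaged within clusters. Dissociation and immediate early genes, which respond to tissue handling, were also lower, in 16 of 22 (median -0.24, -0.28 to -0.18, percentile 0), and Nfkbia, a member of both lists, was at -0.92. Of the Ccl2 UMIs, 58.5% in sham lay in 5 cells, and Ccl2 was at -1.77 without doublet removal. Cxcl1 was at -1.02 averaged within clusters.

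Genes for matrix and for lymphatic growth had medians near 0 in fibroblasts. Of 24 fibrillar collagen and matrix genes, 13 were higher and 11 lower (median 0.03, -0.02 to 0.07). Of 14 measured genes for lymphatic growth factors and their processing, 8 were higher and 6 lower (median 0.04, -0.05 to 0.11, percentile 60.6), with Fgf2 at -0.49, Pgf at 0.47 and Angpt1 at 0.47. Angpt1 was at -0.20 without doublet removal and -0.15 averaged within clusters. The lymphatic growth factor Vegfc, named here after its value was seen, stood at 31.5 CPM in sham and 25.6 CPM in JVL-14 (ratio 0.813, 0.638 to 1.03), and Vegfa had a ratio of 0.993 (0.832 to 1.18). Hypoxia response genes had a median of -0.01 (-0.06 to 0.06) and iron and haem handling genes of -0.01 (-0.07 to 0.09). Basement membrane genes were lower in 10 of 14 (median -0.23), with Lamc1 at -0.70 and Col15a1 at -0.70 (0.49 averaged within clusters for Col15a1), and TGF-beta response genes higher in 11 of 18 (median 0.11, 0.01 to 0.15). Coagulation genes were lower in 7 of 8 (median -0.17) and cholesterol synthesis genes in 6 of 8 (median -0.25). The basement membrane median was 0.08 without cluster 31 (62 sham and 2 JVL-14 cells), that of TGF-beta response -0.06 averaged within clusters, that of coagulation 0.01 in thinned cells, and that of cholesterol synthesis 0.10 without cluster 19.

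Among genes named by the fixed rule in fibroblasts, Fkbp5 (ENSMUSG00000024222), a glucocorticoid-induced co-chaperone, was spread over many cells, with a UMI in 415 of 1408 sham and 62 of 679 JVL-14 cells. Its level was 84.6 CPM in sham and 19.4 CPM in JVL-14 (ratio 0.230, 0.179 to 0.292). The transcription factor Cebpb (ENSMUSG00000056501) stood at 259 and 67.6 CPM (ratio 0.261, 0.229 to 0.297). Both were lower in all 12 alternatives run for them in fibroblasts. Ddit4l was higher (ratio 2.30, 1.95 to 2.70). Tnxb (ratio 0.179), Fbln2 (0.244) and Ccl11 (0.287) were lower in the class as a whole. Tnxb and Ccl11 are leading genes of cluster 31, and averaged within clusters their log2 ratios were 0.14 and 0.11, and that of Fbln2 0.17. That average leaves out cluster 31, and in it genes with few UMIs in a cluster are pulled above 0. It therefore does not show that these genes changed direction. Cluster 31 also lay almost wholly in sham, and whether its cells came from the dura was not tested.

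**Figure D2:**
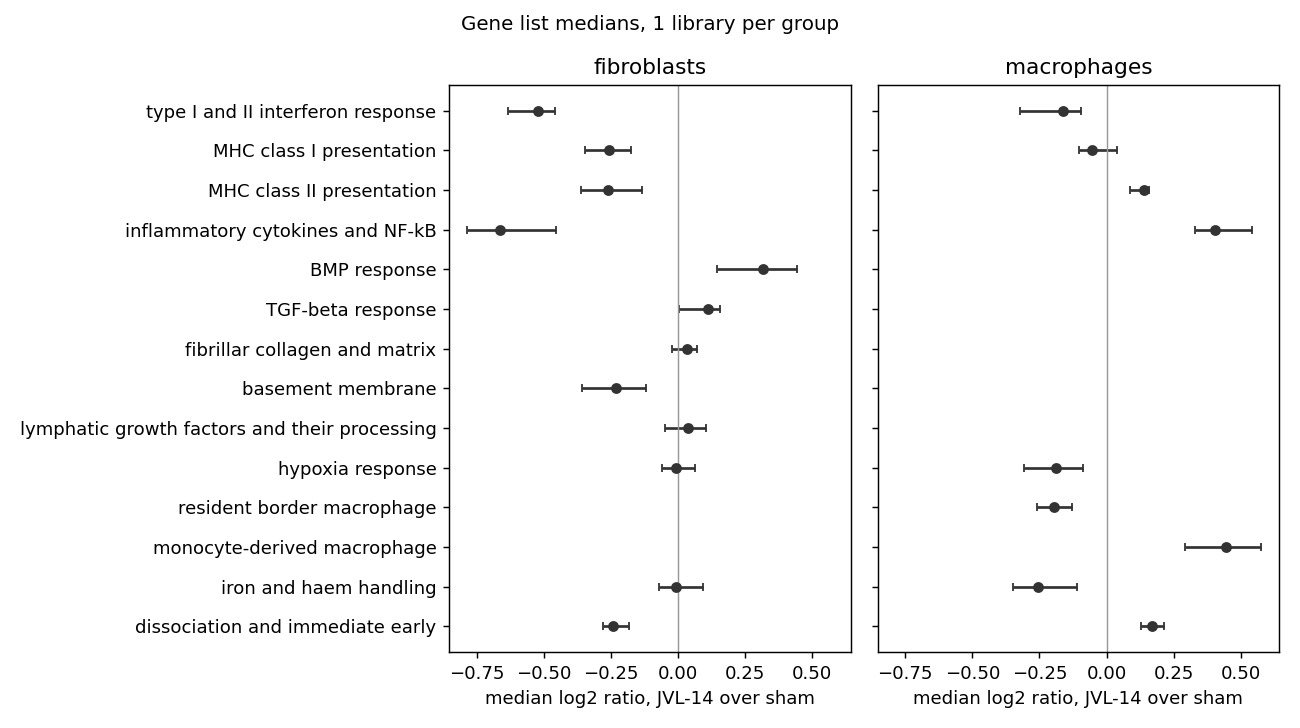
Median log2 ratio JVL-14 over sham of the measured members of each gene list in fibroblasts (left) and macrophages (right), 1 library per group, with 95% intervals for counting error, and lists with too few measured members or not read in a class left blank. The inflammatory list lies at -0.66 in fibroblasts and 0.40 in macrophages, and the BMP list at 0.32 in fibroblasts.

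Macrophages of the JVL-14 library had more transcripts of inflammatory and monocyte-derived macrophage genes and fewer of genes that mark resident macrophages. Of 18 measured inflammatory genes, 16 were higher, 13 beyond counting error (median log2 ratio 0.40, 0.33 to 0.54, percentile 100). The largest were Il1a at 2.39, Cxcl1 at 1.30 and Ptgs2 at 1.14, each with over 50% of its JVL-14 UMIs in 5 cells, and averaged within clusters Cxcl1 was at 0.63 and Ptgs2 at 0.15. Il1b stood at 366 CPM in sham and 574 CPM in JVL-14 (ratio 1.57, 1.42 to 1.73), with 42.4% of its JVL-14 UMIs in 5 cells. The inflammatory median was 0.35 in cluster 2 (290 and 171 cells) and -0.08 in cluster 3 (377 and 154 cells). Dissociation and immediate early genes were higher in 16 of 22 (median 0.17, 0.13 to 0.21), and their median averaged within clusters was -0.05. Mitochondrially encoded genes were lower in 10 of 13 (median -0.15, -0.19 to -0.09, percentile 0.885), with a median of -0.03 at 500 or more genes per cell, and in fibroblasts their median was -0.03. Of 10 monocyte-derived macrophage genes, 8 were higher (median 0.45, 0.29 to 0.57), with Cd9 at 1.04 and the monocyte chemokine receptor Ccr2 at 0.71. With at least 500 genes required per cell, the monocyte-derived median was -0.40, Cd9 was at 0.27 and Ccr2 at -0.19, but there a cluster led by Cx3cr1 and MHC class II genes (163 and 115 cells) stayed unnamed and so left the class.

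Of 16 resident border macrophage genes, 14 were lower (median -0.19, -0.26 to -0.13, percentile 0.18). Lyve1 was at -1.20, Cd209f at -1.05, Folr2 at -0.51 and Cbr2 at -0.50. The resident median was -0.04 with at least 500 genes per cell, where that cluster was also missing. Iron and haem handling genes were lower in 11 of 12 (median -0.26, -0.35 to -0.11), among them the iron exporter Slc40a1 at -0.49, the haemoglobin scavenger Cd163 at -0.46 and Hmox1 at -0.41. MHC class II genes were higher in 8 of 9 (median 0.14, 0.09 to 0.16), with their activator Ciita at 1.22 and Cd74 at 0.22. Interferon response genes were lower in 17 of 21 (median -0.16, -0.32 to -0.09), hypoxia response genes in 11 of 14 (median -0.19, -0.31 to -0.09, with Ddit4 at -1.77), and MHC class I genes in 8 of 12 (median -0.06, -0.10 to 0.04).

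By the fixed rule, the heat shock genes Hspa1b (ENSMUSG00000090877) and Hspa1a (ENSMUSG00000091971) were highest in JVL-14 macrophages, at ratios of 6.42 (5.15 to 8.05) and 3.94 (3.42 to 4.54). Both are members of the dissociation and immediate early list, whose genes respond to tissue handling. Of their JVL-14 UMIs, 43.3% and 36.3% lay in 5 cells. Phlda1 was also among the 5 highest, at 2.92 (2.42 to 3.53). Averaged within clusters Hspa1b was at a log2 ratio of 2.04, and with at least 500 genes per cell Hspa1a was at 1.18. Fkbp5 was again among the lowest genes (125 and 28.9 CPM, ratio 0.230, 0.158 to 0.327), as was Ube2m (65.4 and 18.2 CPM, ratio 0.278, with a log2 ratio of -1.19 as the mean over cells). The pituitary hormone genes Prl (168 and 47.0 CPM) and Gh (78.8 and 16.5 CPM) were also lower, and are genes of another tissue.

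**Figure D3:**
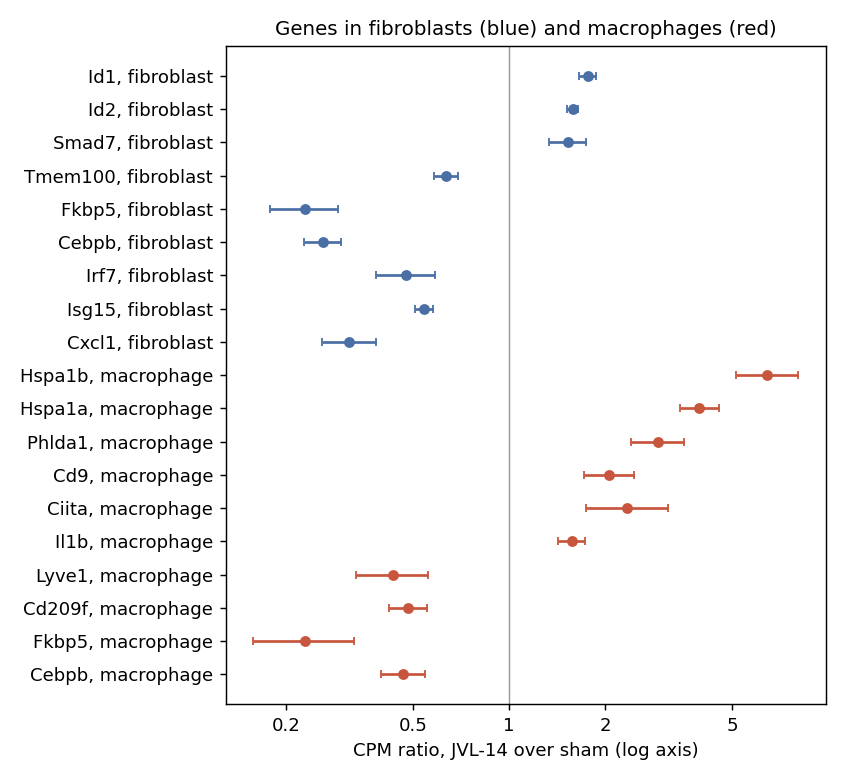
CPM ratio JVL-14 over sham (log axis) of genes in fibroblasts (blue) and macrophages (red), 1 library per group, with exact 95% intervals for counting error. Id1, Id2 and Smad7 lie above 1 in fibroblasts and Hspa1b, Hspa1a and Phlda1 in macrophages, while Fkbp5 and Cebpb lie below 1 in both. Hspa1b and Hspa1a are members of the dissociation and immediate early list.

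Inflammatory genes were also higher in JVL-14 monocytes. This class is cluster 5, led by Cd209a. In 4 alternatives a cluster with Cd209a among its leading genes, of 111 to 139 sham cells, was named dendritic, and the monocyte cluster held 86 to 98 sham cells. Of 16 inflammatory genes, 12 were higher in JVL-14 (median 0.37, 0.19 to 0.44, percentile 100), with Il1b at 0.89 and Cxcl2, against the rest, at -0.96 (0.13 without doublet removal). The inflammatory median was 0.06 as the mean over cells and in thinned cells. Dissociation and immediate early genes were higher in 17 of 21 (median 0.29, 0.22 to 0.35, percentile 100) and mitochondrially encoded genes lower in 12 of 13 (median -0.23, -0.27 to -0.13, percentile 0.14). Hspa1b and Hspa1a, both members of the dissociation list, had ratios of 6.64 (5.10 to 8.72) and 6.21 (4.86 to 7.99). Of their JVL-14 UMIs, 68.1% and 62.1% lay in 5 cells, and Hspa1a was at a log2 ratio of 1.02 with at least 500 genes per cell. Fkbp5 had a ratio of 0.352 (0.214 to 0.552). MHC class II genes were higher in 10 of 13 (median 0.11, percentile 93.1).

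In neutrophils, medians lay near 0 for inflammatory genes (8 of 14 higher, median 0.08, -0.07 to 0.23) and maturation genes (11 of 19 higher, median 0.01, -0.04 to 0.08), with Fpr1 at 0.74 and Retnlg at -0.48. The median of all measured genes in this class was 0.11, and TMM scaling moved log2 ratios by -0.15. Lower by the rule were Tmem243 (ratio 0.225, 0.0986 to 0.452), Hilpda (0.350, 0.238 to 0.503), Ube2m (0.406), Smap1 (0.439) and Plk2 (0.440). In thinned cells Ube2m was at a log2 ratio of -0.68 and Plk2 at -0.49. Mitochondrially encoded genes were lower in 10 of 11 (median -0.35, -0.53 to -0.25) in neutrophils and in 10 of 13 (median -0.13, -0.18 to -0.05) in B cells. Proliferation genes were higher in 10 of 10 (median 1.87), but the median was -0.85 with at least 500 genes and -0.48 with at most 5% mitochondrial UMIs. In B cells, MHC class II genes were lower in 10 of 13 (median -0.15, -0.29 to -0.05), with Cd40 at 0.56 and H2-Eb1 at -0.45. The median of all genes was 0.16, and TMM scaling moved log2 ratios there by -0.15. Wasl (ratio 4.50, 2.02 to 11.3), Pdrg1 (3.28, 1.85 to 6.08), Dut (3.25, 1.92 to 5.72) and Rrp15 (3.10, 1.55 to 6.60) were higher by the rule. Their lowest log2 ratios over the alternatives were 0.93 for Wasl, 1.05 for Pdrg1, 0.22 for Dut and 0.87 for Rrp15. B cell maturation genes had a median of 0.16, near that of all genes. Their member Ighm, the heavy chain of IgM, stood at 21395 and 5721 CPM (ratio 0.267, 0.257 to 0.278), but 73.6% of its sham UMIs lay in 5 cells and its log2 ratio was -0.20 with at least 500 genes per cell. In B cell precursors, proliferation genes were higher in 21 of 22 (median 0.49, 0.45 to 0.66), and the median was -0.28 without doublet removal and -0.12 averaged within clusters.

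Lymphatic endothelial cells, the cells of the vessels that drain the dura, were too few to compare. No cluster took that name. Barcodes with the lymphatic transcription factor Prox1 and either Mmrn1 or Flt4 numbered 2 of 5495 in sham (0.0364%, 0.00441% to 0.131%) and 4 of 3004 in JVL-14 (0.133%, 0.0363% to 0.341%), with intervals that overlap. Among blood endothelial cells, at medians of 1771 and 2294.5 UMIs per cell, a Prox1 UMI was seen in 0 of 168 sham cells, which allows a share of cells with a UMI of up to 1.79%, and in 1 of 46 JVL-14 cells. Cells that express the gene without a UMI are not counted.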

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

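The tests on muscle and choroid plexus cells and on marrow-type cells were chosen after the results were seen.

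Several gene lists went opposite ways in different cell classes, and the differences between classes were not tested. The inflammatory list had a median log2 ratio of 0.40 in macrophages and 0.37 in monocytes but -0.66 in fibroblasts. MHC class II genes were at 0.14 in macrophages, -0.26 in fibroblasts and -0.15 in B cells. Dissociation and immediate early genes were at 0.17 in macrophages, 0.29 in monocytes, 0.27 in neutrophils, 0.37 in B cells, 0.48 in B cell precursors and 0.45 in osteoblast lineage cells, against -0.24 in fibroblasts, -0.55 in neutrophil precursors and -0.33 in Schwann or glial cells. Monocyte-derived macrophage genes were at 0.45 in macrophages and -0.26 in monocytes. The sign of the median turned in at least 1 alternative for dissociation genes in macrophages, osteoblast lineage cells, neutrophil precursors and Schwann or glial cells, for MHC class II genes in fibroblasts, and for monocyte-derived genes in both classes.

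Signals also lay outside the classes compared. Barcodes under the gene minimum with most UMIs from haemoglobin genes were 256 of the sham barcodes (4.66%) and 242 of the JVL-14 barcodes (8.06%), a ratio of 1.73 (1.44 to 2.07). Unnamed cluster 9, led by the pineal and photoreceptor genes Pde6g, Sag, Tph1 and Aipl1, held 52 sham cells and 0 JVL-14 cells.

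Skeletal muscle and choroid plexus cells lay almost wholly in the sham library. Different naming of like cells is argued against, since marker transcripts summed over every barcode differed as much, with the higher of the ratios at 0.0176 (0.0166 to 0.0186). These cells are not part of the dura, so tissue from outside it was in the sham preparation. Why the preparations differ in it stays open. Muscle transcripts in cells of other classes had a ratio of 0.109 (0.0979 to 0.121), near but not under the 0.1 set for carry-over. That test cannot decide the reason, since muscle RNA in other cells goes with muscle cells in the suspension. A difference made by the ligature cannot be told apart from one of dissection with 1 library per group.

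B lineage, erythroid and neutrophil precursor shares were higher in JVL-14. For the B lineage, a sham denominator enlarged by outside tissues is argued against as the whole cause, since its ratio without those tissues was 1.93 (1.66 to 2.23). This value follows from cell counts already seen and is no separate test. It does not cover the erythroid and neutrophil precursor shares. More carry-over of skull marrow cannot be told apart from an effect of the ligature. The share ratio of Camp-high neutrophils was 0.535 (0.363 to 0.781) times that of B cell precursors, but this interval covers counting error only and leaves out how far preparations differ, and neutrophil precursors had a ratio of 2.71, near the 2.25 of B cell precursors. Without doublet removal, where 21 and 7 cells kept the name of neutrophil precursors, their ratio was 0.633 (0.227 to 1.55). Over the alternatives it ran from 0.633 to 2.71, so how near it lay to 2.25 depends on the setting.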

How the results depend on the processing

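The settings that average within clusters, leave out clusters of 1 library or fibroblast cluster 19, leave out tissues outside the dura or place unnamed clusters in their best-scoring class were chosen after the data were seen. No paired analysis was possible because each group has 1 library and no test was made. Where a value below differs from that in the report, the cause was not tested.

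Fkbp5 (-2.55 to -1.60) and Cebpb (-2.29 to -1.77) in fibroblasts kept their direction in every setting run, as did Id1 (0.48 to 1.01), Id2 (0.44 to 0.79), Smad7 (0.51 to 0.79), the BMP list (0.12 to 0.42) and the B lineage share ratio (1.87 to 2.41). Of values for single genes, 657 stayed within counting error, 183 lay beyond it and 17 changed sign, where a sign change is counted only beyond counting error and for values whose interval left out no difference. For shares and lists that answer a comparison these numbers were 51, 5 and 1 and 58, 18 and 2, and for other shares and lists 101, 16 and 2 and 361, 119 and 24.

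With the libraries clustered separately, share ratios were 0.491 for neutrophils, 2.41 for the B lineage, 0 for skeletal muscle, monocytes and natural killer or innate lymphoid cells, 3.47 for T cells and 1.22 for unnamed cells. The endothelial share ratio lay between 0.494 and 0.848. The neutrophil ratio of 0.491 lay below 1, but there a JVL-14 cluster of 64 cells that scored best as neutrophils stayed unnamed. The sham cluster led by Camp (98 cells) was named. This ratio is not counted as a sign change because its interval in the report held 1. Without marrow classes the fibroblast ratio was 1.02. With at least 500 genes per cell, share ratios were 0.743 for macrophages and 4.90 for erythroid cells, and log2 medians were -0.45 for fibroblast interferon, 0.31, -0.035 and -0.40 for macrophage inflammatory, resident and monocyte-derived genes, -0.85 for neutrophil proliferation and 0.36 for Schwann or glial dissociation genes, with Ccr2 in macrophages at -0.19 and Klf2 in endothelial cells at -0.11. Without doublet removal, the neutrophil precursor ratio was 0.633, where 21 sham and 7 JVL-14 cells kept that name. Log2 values in that setting were -0.20 for Angpt1 in fibroblasts, 0.13 for Cxcl2 in monocytes, -0.037 for Klf2 and 0.47 for Cxcl10 in endothelial cells, -0.28 for B cell precursor proliferation and 0.65 for neutrophil precursor dissociation genes.

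Averaged within clusters, fibroblast medians were 0.011 for interferon, -0.12 for inflammatory, -0.056 for TGF-beta and 0.21 for MHC class II genes, with Tnxb at 0.14, Fbln2 at 0.17, Ccl11 at 0.11, Irf7 at 0.24, Isg15 at 0.072, Col15a1 at 0.49 and Angpt1 at -0.15. Macrophage inflammatory genes were at 0.18 and dissociation genes at -0.052, B cell precursor proliferation at -0.12 and Schwann or glial dissociation genes at 0.28. Without cluster 19, fibroblast interferon genes were at -0.17 and cholesterol synthesis at 0.10. Without clusters of 1 library, fibroblast inflammatory genes were at -0.44, basement membrane at 0.080, Fbln2 at 0.29 and Col15a1 at 0.55. With unnamed clusters in their best-scoring class, fibroblast interferon genes were at -0.36 and inflammatory genes at -0.44.

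As the mean over cells, fibroblast interferon genes were at -0.37 and MHC class II at 0.10, and macrophage inflammatory genes at 0.56 and monocyte-derived at 0.27. In cells thinned to 1000 UMIs, which left out 118 sham and 59 JVL-14 fibroblasts and 113 and 52 macrophages, fibroblast interferon genes were at -0.40, coagulation at 0.0072 and MHC class II at 0.10, macrophage inflammatory at 0.57 and resident at -0.29, B cell maturation at -0.11, Klf2 at -0.14 and Schwann or glial dissociation genes at 0.065. With classes from the marker score of each cell, fibroblast interferon genes were at -0.78, macrophage resident at -0.10, monocyte-derived genes in monocytes at 0.062, B cell maturation at -0.14 and osteoblast lineage dissociation genes at -0.34. With at most 5% mitochondrial UMIs, neutrophil proliferation was at -0.48, B cell maturation at -0.090, Klf2 at -0.086, and dissociation genes at -0.34 in osteoblast lineage cells and 0.11 in neutrophil precursors. With every member counted the BMP median was 0.12, and with the median of ratios B cell maturation was at -0.056.

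The median of all genes moved by over 0.1 under TMM and the median of ratios in neutrophils (-0.15 and -0.18), B cells (-0.15 and -0.22), endothelial cells (-0.17 and -0.14) and B cell precursors (0.11 and 0.10). Depth limits what counting error allows to be seen: in simulated B cells 73% of genes changed 2-fold had an interval on the right side of 1. The simulated counts had no spread between cells, so this is no detection limit for the real data.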

Other observations

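The tests of glucocorticoid exposure, time of day and GC content were set before their results were seen, while the genes of the pattern and the endothelial genes outside the fixed rules were chosen after.

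Blood endothelial cells, with 46 cells in JVL-14, were under the minimum for a comparison, and their values are given as such. Venous endothelial genes were higher in 11 of 13 (median log2 ratio 1.68, with a lower interval end of 1.43, percentile 100), and the median was 0.72 with at least 500 genes per cell. Dissociation and immediate early genes were also higher in these cells, in 16 of 21 (median 0.39, 0.22 to 0.53, percentile 99.97). Mitochondrially encoded genes were higher in 10 of 13 (median 0.21, 0.13 to 0.33). Vwf, a clotting factor carrier stored in endothelial cells, had 52 and 68 UMIs (ratio 4.12, 2.83 to 6.03), but only 8 JVL-14 cells held a UMI and 92.7% of the UMIs lay in 5 cells. Without doublet removal the log2 ratio of Vwf was 0.97 and that of Cldn5 0.91. The adhesion molecules Icam1 and Vcam1 had ratios of 5.96 and 4.65, and the tight junction gene Cldn5 of 3.13, with 73.5%, 100% and 71.6% of their JVL-14 UMIs in 5 cells. With at least 500 genes per cell, log2 ratios were 0.04 for Vcam1 and 0.72 for Icam1. Endothelial activation and leukocyte adhesion genes as a list were higher in 2 of 8 (median -0.15, -0.58 to 0.21, percentile 10.4). Among them Cd74 had 180 and 12 UMIs (log2 ratio -2.20, and -0.57 as the mean over cells), and Cxcl10 had 81 UMIs, all in 4 sham cells, and 0 in JVL-14 (log2 ratio 0.47 without doublet removal). Cluster 22, with capillary genes such as Gpihbp1 and Car4 in the lead, held 71 sham and 3 JVL-14 cells, and whether they came from the dura was not tested. In cluster 12 alone (97 and 43 cells), the ratios were 3.31 for Vwf, 4.86 for Icam1, 3.58 for Vcam1 and 3.03 for Cldn5. Flow and shear response genes were higher in 6 of 15 (median -0.05, -0.33 to 0.25), junction genes in 8 of 15 (median 0.01) and arterial genes in 8 of 13 (median 0.27, -0.05 to 0.60). The flow-induced factors Klf2 and Klf4 had ratios of 1.19 and 0.843, and Klf2 was lower in 4 of 9 alternatives (log2 ratio down to -0.14).

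Antibody-secreting cells were few. Barcodes with at least 10 UMIs of Jchain, the joining chain of secreted antibodies, numbered 12 of 5495 (0.218%, 0.113% to 0.381%) in sham and 2 of 3004 (0.0666%, 0.00806% to 0.240%) in JVL-14, with intervals that overlap. In the B cell class they were 6 of 198 (3.03%, 1.12% to 6.48%) and 0 of 191, which allows a share of up to 1.57%.

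Fkbp5, Cebpb and Zbtb16 were lower in JVL-14 fibroblasts and macrophages, and Nr1d1 in fibroblasts, and averaged within clusters Zbtb16 in macrophages was at -0.50. Zbtb16 lay under the limit for a measured gene in both classes, with 148 and 12 UMIs in fibroblasts and 39 and 3 in macrophages. Nr1d1 did so in macrophages, with 10 and 6 UMIs. GC content is argued against, since genes of like GC content had median log2 ratios between -0.05 and 0.05 in all 20 bins of both classes, and taking these off moved the less negative of the class medians only from -1.60 to -1.59. Each class median was over all 4 genes, those under the limit included. As a hypothesis, lower glucocorticoid exposure in the JVL-14 mice may contribute: of 15 other glucocorticoid-induced genes, 6 were measured in fibroblasts and all 6 were lower (median -0.56, -0.71 to -0.41, percentile 0.02), with Cdkn1a at -1.08 and Bcl6 at -0.69. In macrophages their median was -0.19 (-0.43 to 0.08), and dissociation and immediate early genes were at -0.24 in fibroblasts (percentile 0) and 0.17 in macrophages, so a difference in handling, which was not tested against these genes, stays open. Inflammatory genes were also lower in fibroblasts (median -0.66, and -0.12 averaged within clusters), which the glucocorticoid prediction did not cover. Another time of day at dissection cannot be told apart, since clock genes in phase with Nr1d1 less those in the opposite phase gave -0.28 (-0.54 to 0.11) over 6 genes. The medians of the other glucocorticoid-induced genes and of the clock genes were not run under the alternatives.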
